A study of Mus musculus with 21 samples.

How the data were processed

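RNA-seq libraries of 21 samples of the mouse SHH medulloblastoma line SMB21 were used. Per the labels' protocols, cells grew in DMEM/F12 with B-27, RNA was isolated with an RNeasy kit, and TruSeq Stranded mRNA libraries from 500 ng of total RNA were pooled in equal amounts and sequenced as single-end 75 bp reads in 2 runs of a NextSeq 500. Per the submitters' processing notes, reads were aligned with STAR 2.5.1b to mm9. The values the authors deposited are raw read counts per gene symbol, 1 column per library, as the whole numbers and unequal column sums show. The strand counted, the annotation and the handling of reads that map to several places are not given in the sources used here, so values of close paralogs and of overlapping or antisense genes are uncertain. The table has 24047 genes, 4115 of them with no count in any library. In 14 rows the gene name has the form of a date, as spreadsheets write it. These hold 0.265% of all counts, and were kept in the tests and never named.

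Samples were grouped by their labels into DMSO 2 h, JNJ 2 h, DMSO 24 h, JNJ 24 h, shLuc, shHdac1 and shHdac2, with 3 libraries each. Total counts per library were 35623027 to 39341784 in DMSO 2 h, 28465310 to 38401504 in JNJ 2 h, 33829963 to 37888863 in DMSO 24 h and 23461048 to 33608651 in JNJ 24 h. They were 23094799 to 26738741 in shLuc, 23808461 to 31907047 in shHdac1 and 25122173 to 31426312 in shHdac2. Between 15510 and 17301 genes had counts in a library, and the 50 genes with most counts held 6.50 to 9.67% of a library. At these depths 3 counts, the floor used here per library, are 0.0763 to 0.13 CPM. Floors and counting intervals cover counting error only.

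The JNJ and DMSO libraries (12) and the shRNA libraries (9) were fitted apart with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 14467 and 13612. Libraries were scaled by TMM (factors 0.883 to 1.15 and 0.961 to 1.03), dispersions were estimated (common biological coefficient of variation 0.294 and 0.209), and quasi-likelihood tests, two-sided, were adjusted by Benjamini-Hochberg over all genes tested. A gene was called at an adjusted p under 0.05. The fit used group as its only term. The comparisons were JNJ against DMSO at 2 h and at 24 h, the difference of these effects, DMSO 24 h against 2 h, each knockdown against shLuc, and shHdac1 against shHdac2. CPM are edgeR's on the scaled totals, within each of both fits. Standard errors are of the log2 change. A replicate number was taken to pair libraries where residuals of libraries with the same number correlated above 0.1, which held at 24 h and for the shRNA groups. The tests above did not use this pairing, and a replicate block was fitted as another setting. In the shRNA groups, replicates 1 and 2 also correlated across numbers. For example, shLuc replicate 2 had 0.322 with shHdac1 replicate 1 and 0.245 with shHdac1 replicate 2. There the number parts replicate 3 from replicates 1 and 2 more than it pairs libraries.

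20 gene lists were written from general knowledge, and each list needed 5 tested members. They are hedgehog targets, hedgehog pathway components, HDAC genes, HDAC1 and HDAC2 co-repressor subunits, inhibitors of cyclin-dependent kinases, G1/S and replication, G2/M and mitosis, pro-apoptotic genes, p53 targets, the cerebellar granule lineage, neuronal differentiation and synapse, REST targets, glial genes, non-neural cell markers, ribosome biogenesis and MYC targets, interferon response, MHC class I presentation, immediate-early genes, genes often raised by HDAC inhibitors, and homologous recombination and checkpoint. 2 members are not in the table. Some genes are in more than 1 list. Lists were tested with camera of limma 3.58.1 (preset correlation 0.01), adjusted by Benjamini-Hochberg over the lists of a comparison, and again with an estimated correlation and with fry. fry tests whether a list's genes move on balance 1 way, not whether they move more than other genes. The genes most clearly changed with JNJ at 24 h (200 each way by p-value) were tested as sets in the knockdowns, with adjustment over these 4 tests.

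Genes were named by a rule. It takes Hdac1 and Hdac2 everywhere. It takes the 6 genes that rose and fell most in the JNJ and shLuc comparisons (4 in the others), among called genes with a mean of at least 5 CPM and no overlap between the libraries of the groups. For the difference between times, the overlap was not asked for. Placeholder symbols were counted but passed over. In the JNJ and shLuc comparisons the rule adds Gli1, Ptch1, Hhip, Mycn, Ccnd1, Atoh1, Cdkn1a and H1f0, and the 2 called members with the lowest p in the direction of each list called by camera. Some genes that the rule names are not reported here. Genes named beyond this rule are said to be so where they appear.

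Groups, comparisons, tests, lists, the naming rule and a first series of other settings were set before the data were examined. That series held RLE, upper-quartile and total-count scaling, no filter or a stricter one (1 CPM in 3 libraries), DESeq2 1.42.0, limma-voom, a replicate block, all 21 libraries in 1 fit, only the libraries of the groups compared, leaving out each library, an adjusted p under 0.01, and sets of 50 or 500 genes. Added after seeing the data were fits without the shRNA libraries numbered 3, with replicates 1 and 2 summed, with a term for the ribosomal RNA-linked split of the libraries, on the high side of that split alone, and with a block in the compared groups only. Lists under RLE and upper-quartile scaling and without DMSO 2 h replicate 1 or the shRNA libraries numbered 3, and the sets with an estimated correlation and without those libraries, were also added then.

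The calls were tested on counts simulated independently per library, from means and dispersions fitted to the real libraries. In these, 64 to 67 genes were changed at each of 3 sizes per comparison and 1 list was raised. The draws lack the closeness of replicates 1 and 2 in the shRNA groups and the ribosomal RNA-linked split. The shares called and the false calls may therefore not hold for the shRNA comparisons. Far fewer genes were changed than the JNJ comparisons called (1982 at 2 h and 4791 at 24 h). The Benjamini-Hochberg adjustment is stricter where fewer genes change, so the shares called may be too low for the JNJ comparisons. At a 2-fold change edgeR called 31.8% of changed genes in the JNJ 2 h groups, 36.4% at 24 h, 53.7% with shHdac1, 59.1% with shHdac2 and 4.62% for the difference between times. At 4-fold these were 76.6, 73.8, 80, 83.3 and 56.1%. None was called in the wrong direction and 1 to 10 unchanged genes were called. So a gene that is not called may have changed, above all in the difference between times. No library and no gene that passed the filter was left out of the tests.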

Results

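RNA was sequenced from SMB21 cells, a mouse line of sonic hedgehog (SHH) medulloblastoma, with inhibitors of class I histone deacetylases as the theme of the series. Cells received the histone deacetylase (HDAC) inhibitor quisinostat (JNJ) or its solvent DMSO for 2 h or 24 h. Other cells received a virus coding for a short hairpin RNA (shRNA) against luciferase (shLuc), Hdac1 or Hdac2, followed by puromycin. Each of the 7 groups has 3 libraries, 21 in all, with 23094799 to 39341784 counted reads per library (median 31426312). The libraries of each group are numbered 1 to 3 in the labels. Nothing in the labels says whether the 3 libraries of a group came from separate cultures, so every p-value measures the spread between these libraries, which may be technical.

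The first principal component of the depth-scaled log2 read counts (log2 CPM) held 35.4% of the variance over 14511 genes and set the JNJ 24 h libraries apart, at 97.8 to 103. The JNJ 2 h libraries lay from -10.6 to 39.04 and all 6 DMSO libraries from -44.7 to -17.9. Among the shRNA libraries, shLuc replicate 3 lay at -57.2, against 3.43 and 2.72 for shLuc replicates 1 and 2. The shHdac1 libraries lay at -28.8 to -26.7 and the shHdac2 libraries at -18.2 to -4.83.

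**Figure D1:**
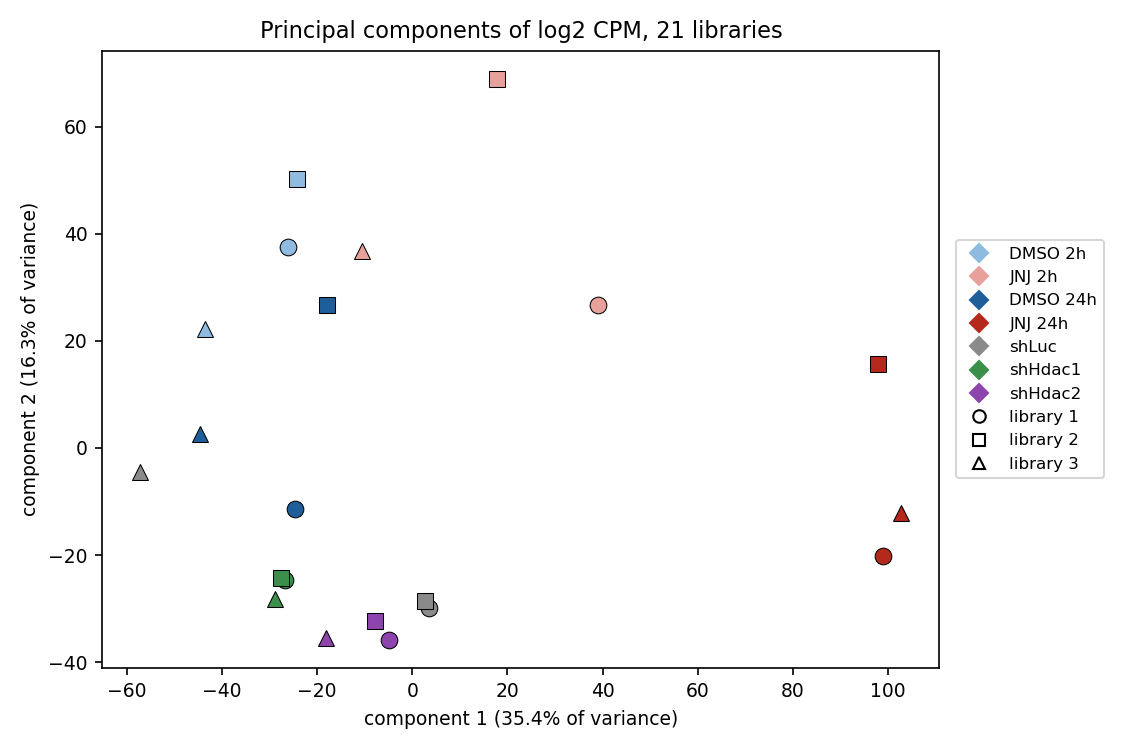
Each point is 1 of the 21 libraries, placed by the first principal component (x axis, 35.4% of variance) and the second (y axis, 16.3%) of log2 CPM, with colour for the group and symbol for the replicate number. The JNJ 24 h libraries lie at 97.8 to 103 on the first component, above all others.

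After 2 h with JNJ, Gata2 rose, Atoh1 and Ccnd1 fell, and Gli1 was not called. Gata2, a transcription factor gene of blood and neural lineages, rose 16.9-fold (log2 4.08, SE 0.43, adjusted p = 0.000286), from 0.654 ± 0.250 to 11.1 ± 3.08 CPM (mean ± SD, n = 3 per group). Atoh1, the proneural gene that keeps granule neuron progenitors dividing, fell from 457 ± 78.5 to 187 ± 23.6 CPM (log2 -1.29, SE 0.20, adjusted p = 0.0017). Ccnd1, which encodes cyclin D1, a target of SHH signalling, fell from 911 ± 219 to 409.6 ± 64.4 CPM (log2 -1.15, SE 0.24, adjusted p = 0.00735). Gli1, the usual readout of the pathway, was not called: 129.6 ± 30.8 against 131 ± 28.8 CPM (log2 -0.01, adjusted p = 0.981).

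At 2 h, 1318 genes were higher and 664 lower of 14467 tested, and 853 and 251 of these changed at least 2-fold. The libraries of the 2 groups did not overlap for 25.6% of genes, where chance gives 10%. Among genes with a mean of at least 5 CPM whose groups do not overlap, other large rises were in Tmem86a (13.6-fold), S1pr2 (13.4-fold), Fgfr3 (11.8-fold) and Efna3 (10.5-fold, 118 ± 31.6 against 11.2 ± 2.01 CPM). Fgfr3 encodes a growth factor receptor and Efna3 an ephrin of cell contact signalling. The largest falls among such genes were in Kdm8 (log2 -2.63, SE 0.31), Bhlhe22 (-2.44), Dtwd2 (-2.39), Zbtb38 (-2.29), C2cd4b (-2.22) and Iba57 (-2.14). The count of called genes was 1144 without DMSO 2 h replicate 1, 1063 without DMSO 2 h replicate 2, 1043 without JNJ 2 h replicate 1 and 3365 without JNJ 2 h replicate 3. The share of called genes that were higher, 66.5%, was 54.5% with upper-quartile scaling.

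Of the HDAC genes that the hairpins target, Hdac1 was not called at 2 h and Hdac2 fell. Hdac1 had 93.8 ± 15.8 CPM against 95.4 ± 9.05 in DMSO (log2 -0.02, adjusted p = 0.946). Hdac2 fell from 380.2 ± 20.0 to 259.5 ± 52.6 CPM (log2 -0.55, SE 0.16, adjusted p = 0.0376). That call was lost without any 1 of DMSO 2 h replicates 1, 2 and 3 (adjusted p = 0.0847, 0.0670 and 0.0790) or JNJ 2 h replicates 1 and 2 (0.116 and 0.0985). Cdkn1a, the cell cycle inhibitor gene that HDAC inhibitors are known to induce, rose 2.23-fold at 2 h (198 ± 74.0 against 89.1 ± 17.8 CPM, log2 1.15, SE 0.33, adjusted p = 0.0353). Its call was lost without any 1 of DMSO 2 h replicates 1, 2 and 3 (0.148, 0.105 and 0.0588) or JNJ 2 h replicates 1 and 3 (0.0660 and 0.0873). H1f0, a linker histone gene with the same reputation, was not called (log2 0.64, adjusted p = 0.0971).

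Of the hedgehog genes looked up by rule, Hhip (log2 0.40, adjusted p = 0.378), Ptch1 (0.14, 0.705) and Mycn (-0.86, 0.196) were not called. In the list of 16 hedgehog target genes, 1 rose, 2 fell and 13 were not called at 2 h, with the same counts when adjusted over the list alone (median log2 -0.14, camera adjusted p = 0.211). None of 23 hedgehog pathway components was called by edgeR (median log2 -0.07, camera adjusted p = 0.85).

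camera was run on 20 lists of genes per comparison, and called 5 of them at 2 h. Cerebellar granule lineage genes were lower as a list: 4 of 22 fell, none rose and 18 were not called, with the same counts adjusted over the list alone (median log2 -0.50, adjusted p = 0.00208; adjusted p = 0.727 with an estimated correlation). They include Insm1, a transcription factor gene of dividing neural progenitors, at 31.7 ± 11.8 against 120.5 ± 22.5 CPM (log2 -1.92, SE 0.33), and Atoh1. Of 28 ribosome biogenesis and MYC target genes 1 rose, 3 fell and 24 were not called, also when adjusted over the list alone (median -0.35, adjusted p = 0.00574; 0.84 with an estimated correlation). Myc (log2 -1.18, adjusted p = 0.00856) and Ncl (log2 -0.70, adjusted p = 0.0149), which encodes nucleolin, fell. The Ncl call was lost without JNJ 2 h replicate 2 (adjusted p = 0.0597).

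The G1/S list was also lower at 2 h, with 2 genes up, 1 down and 33 not called, also when adjusted over the list alone (median log2 -0.34, adjusted p = 0.0239; 0.84 with an estimated correlation). Ccne2, which encodes cyclin E2 of S-phase entry, was the member that fell (81.1 ± 14.3 to 42.5 ± 5.24 CPM, log2 -0.93, SE 0.23, adjusted p = 0.0191). Its call was lost without DMSO 2 h replicate 3 (adjusted p = 0.0572) and without JNJ 2 h replicates 1 or 2 (0.0602 and 0.0633). Targets of REST, the repressor of neuronal genes, were higher as a list: 6 of 33 rose (7 adjusted over the list alone), none fell and 27 were not called (median 0.39, adjusted p = 0.0199; 0.84 with an estimated correlation). Bdnf, a neurotrophin gene, rose 6.44-fold (SE 0.36, adjusted p = 0.0008) and Vgf, a secreted neuropeptide precursor gene, 7.36-fold (SE 0.40, adjusted p = 0.00101).

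Of 17 genes of MHC class I antigen presentation, 4 rose at 2 h (5 adjusted over the list alone), none fell and 13 were not called (median log2 0.78, adjusted p = 0.0268; 0.84 with an estimated correlation). Tap2, a peptide transporter gene, rose 4.30-fold (SE 0.50, adjusted p = 0.0154) and Tapbp, its partner tapasin, had a log2 of 0.96 (SE 0.26, adjusted p = 0.0262). The Tap2 call was lost without DMSO 2 h replicates 1 or 3 (adjusted p = 0.0702 and 0.0537) and JNJ 2 h replicate 1 (0.0750). The Tapbp call was lost without DMSO 2 h replicates 1, 2 or 3 (0.114, 0.0642 and 0.0537) and JNJ 2 h replicate 1 (0.124).

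Of 23 pro-apoptotic genes, 8 rose at 2 h and none fell (8 and 1 adjusted over the list alone), and 15 were not called. The list as a whole was not called by camera (median log2 0.19, adjusted p = 0.12) but was called higher by fry (adjusted p = 0.0109). The genes that rose are meant in what follows. They include Bik (log2 2.16) and Bmf (1.78), BH3-only killer genes, both chosen after their values were seen. Of 24 p53 target genes 5 rose, none fell and 19 were not called, with the same counts adjusted over the list alone (median 0.19, adjusted p = 0.246). Of 30 immediate-early genes 4 rose and 3 fell, also when adjusted over the list alone (median 0.37, adjusted p = 0.674). The median and the test differed in sign for HDAC genes (median 0.08, tested lower, adjusted p = 0.688) and interferon-stimulated genes (median -0.02, tested higher, adjusted p = 0.688).

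After 24 h with JNJ, Mcm3, Gli1 and Hhip fell and Slc17a7 rose. Mcm3, part of the replication helicase, fell from 408 ± 11.9 to 103 ± 26.9 CPM (log2 -1.99, SE 0.20, adjusted p = 5.16e-05, n = 3 per group). Gli1 fell from 166 ± 31.6 to 96.1 ± 22.9 CPM (log2 -0.79, SE 0.24, adjusted p = 0.0236). Hhip, a hedgehog-binding protein gene that the pathway induces, fell from 58.9 ± 16.1 to 24.9 ± 4.44 CPM (log2 -1.24, SE 0.29, adjusted p = 0.00591). Slc17a7, the vesicular glutamate transporter gene of mature granule neurons, rose 22.97-fold (SE 0.30 on the log2 scale, adjusted p = 4.6e-06).

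At 24 h, 2613 genes were higher and 2178 lower of 14467 tested, and 1952 and 849 of these changed at least 2-fold. The groups did not overlap for 55.5% of genes, where chance gives 10%. The lower count was 1426 without JNJ 24 h replicate 3. The median log2 of all genes was 0.01, and 0.17 when libraries were scaled by their totals or 0.12 by upper quartile. The higher genes' share, 54.5%, was then 68.3% or 63.8%. No called gene named here and no called list changed direction with those scalings, but Gli1 was no longer called by library totals (adjusted p = 0.0647). The Gli1 call was also lost without DMSO 24 h replicates 1 or 2 (0.0860 and 0.0510) and without JNJ 24 h replicates 2 or 3 (0.0578 and 0.1001). These fits did not pair the libraries by number. With a replicate block, which does, 3509 genes were higher and 3124 lower at 24 h, and all 4791 calls made without it were held. Direction at 24 h went with expression level. Of the 10% of tested genes with the highest shLuc level, 31.5% fell and 3.59% rose (median log2 -0.32). Of the 10% with the lowest, where the filter favours genes high in a drug group, 41.4% rose and 1.87% fell. The list tests took no account of expression level.

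Among genes with a mean of at least 5 CPM whose groups do not overlap at 24 h, Itpr3, a calcium release channel gene, rose 266-fold (42.5 ± 18.5 against 0.155 ± 0.0224 CPM, log2 8.06, SE 0.52, adjusted p = 4.6e-06). The MHC class II gene H2-Ab1 had 971 counts in the JNJ libraries and 4 in the DMSO libraries, a ratio of 311 in CPM with an exact 95% counting interval of 121 to 1142 (adjusted p = 3.13e-05). Ppm1j rose 85.7-fold, Klc3 75.4-fold, Scube1 49.1-fold and Ret, a receptor tyrosine kinase gene of neural crest and neurons, 74.6-fold (22.8 ± 4.18 against 0.301 ± 0.0665 CPM, log2 6.22, SE 0.51). The largest falls among such genes were in Rcbtb2 (97.0 ± 9.48 to 7.19 ± 2.14 CPM, log2 -3.75, SE 0.32), S100b (-3.48), Hamp2 (-3.11), Lrrc4 (-3.001), Apod (-2.97) and Ccne2 (-2.84, SE 0.25, 88.0 ± 19.3 to 12.2 ± 3.48 CPM). Hamp2 has a close paralog, and how reads that map to both were counted is not stated, so its value is uncertain. The same holds for H2-Ab1 and the other H2 genes.

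Neither HDAC gene was called at 24 h: Hdac1 had 128 ± 21.8 against 93.8 ± 7.94 CPM (log2 0.45, adjusted p = 0.0608) and Hdac2 303 ± 3.82 against 373 ± 17.9 CPM (log2 -0.30, adjusted p = 0.168). With a replicate block, which pairs the 24 h libraries by number, Hdac1 was called higher (log2 0.44, adjusted p = 0.01395) and Hdac2 was not called (-0.30, 0.0994). With a block in the compared groups only, added after seeing the data, Hdac2 was called lower (adjusted p = 0.0101). Cdkn1a rose 3.49-fold (307 ± 130.0 against 88.0 ± 24.4 CPM, SE 0.34, adjusted p = 0.00159) and H1f0 2.49-fold (SE 0.24, adjusted p = 0.00152).

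Hedgehog target genes were lower as a list at 24 h: 7 of 16 fell, none rose and 9 were not called (7 fell and 1 rose adjusted over the list alone; median log2 -0.59, camera adjusted p = 0.00464; 0.369 with an estimated correlation). Ccnd1 fell from 1098 ± 69.9 to 410.4 ± 119 CPM (log2 -1.42, SE 0.24, adjusted p = 0.000908) and Atoh1 from 475 ± 74.5 to 225 ± 45.2 CPM (-1.08, SE 0.20, adjusted p = 0.00161). Foxm1, a mitotic transcription factor gene, had a log2 of -1.41 (adjusted p = 0.00152) and Bmi1, a polycomb gene, -1.33 (adjusted p = 0.00123). Ptch1 (log2 0.03, adjusted p = 0.942) and Mycn (-1.04, 0.0761) were not called, but Mycn was with a replicate block (-1.09, adjusted p = 0.00112). Of 23 pathway components 2 rose, 4 fell and 17 were not called, also when adjusted over the list alone (median -0.07, adjusted p = 0.313). The signal transducer Smo (-1.34) fell and the co-receptor Cdon (1.38) rose, both chosen after their values were seen.

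**Figure D2:**
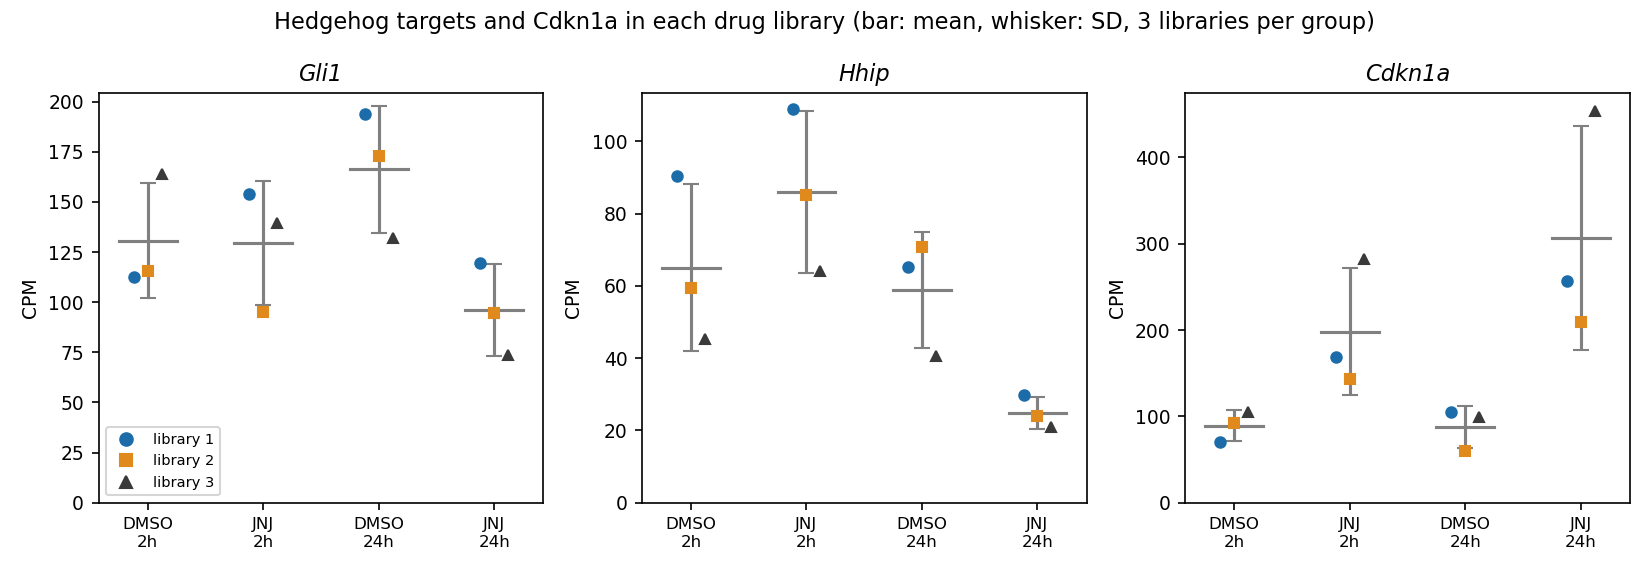
CPM (y axis) of Gli1, Hhip and Cdkn1a in the DMSO and JNJ libraries at 2 h and 24 h (x axis), where points are libraries with a symbol per replicate number, bars the means and whiskers the SD. At 24 h, Gli1 is 96.1 ± 22.9 CPM with JNJ and 166 ± 31.6 with DMSO, while at 2 h it is 129.6 ± 30.8 and 131 ± 28.8. By edgeR the difference between times was called for Hhip (adjusted p = 0.0406), but not for Gli1 or Cdkn1a.

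The G1/S list had the lowest median of the 20 lists at 24 h. Of 36 G1/S genes 34 fell (35 adjusted over the list alone), none rose and 2 were not called (median log2 -1.30, adjusted p = 8.79e-28; 0.0946 with an estimated correlation). Of 34 G2/M genes 25 fell (27 adjusted over the list alone), none rose and 9 were not called (median -0.84, adjusted p = 3.84e-09; 0.369 with an estimated correlation). Ube2c, which helps to end mitosis, had a log2 of -1.29 (adjusted p = 0.00187). Of 25 homologous recombination genes 20 fell (21 adjusted over the list alone), none rose and 5 were not called (median -1.12, adjusted p = 6.59e-11; 0.369 with an estimated correlation). They include the checkpoint kinase gene Chek1 (log2 -1.998, adjusted p = 8.16e-05) and the end resection gene Rbbp8 (-1.61, adjusted p = 0.000235). Of 28 ribosome biogenesis and MYC target genes 13 fell (14 adjusted over the list alone), none rose and 15 were not called (median -0.58, adjusted p = 8.6e-06; 0.369 with an estimated correlation). Nop56 (log2 -1.36, adjusted p = 0.000403) and Ncl (-1.14, adjusted p = 0.000402) were among them.

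Cerebellar granule lineage genes were lower as a list at 24 h too: 6 of 22 fell (7 adjusted over the list alone), 1 rose and 15 were not called (median log2 -0.33, adjusted p = 0.0162; 0.369 with an estimated correlation). Besides Atoh1, Zic4, a cerebellar transcription factor gene, fell (log2 -1.22, adjusted p = 0.000857). The granule lineage list was not tested against genes of like expression. By shLuc level, the share of tested genes that fell ran from 1.87% of the lowest 10% to 31.5% of the highest 10%. Where the granule lineage genes lie in that range was not examined. Neuronal differentiation genes were higher as a list, with 16 of 36 rising, 3 falling and 17 not called, also when adjusted over the list alone (median 0.48, adjusted p = 0.00464; 0.369 with an estimated correlation). Besides Slc17a7, Mapt, the microtubule protein tau gene, rose 7.46-fold (SE 0.35, adjusted p = 0.000127). The 3 members that fell were Dcx (log2 -1.37), Nsg1 (-1.31) and Stmn3 (-0.60), named after their values were seen. Of 33 REST targets 15 rose (16 adjusted over the list alone), 1 fell and 17 were not called (median 0.92, adjusted p = 0.00084; 0.369 with an estimated correlation). Vgf rose 18.2-fold (SE 0.43) and the secretory granule gene Chga 6.99-fold (SE 0.37).

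Antigen presentation genes were higher as a list at 24 h: of 17 MHC class I genes 12 rose, 3 fell and 2 were not called, also when adjusted over the list alone (median log2 2.31, adjusted p = 0.000373; 0.369 with an estimated correlation). Tap2 rose 27.4-fold (SE 0.55, adjusted p = 0.000101) and Psmb9, an immunoproteasome subunit gene, 27.2-fold (SE 0.57, adjusted p = 0.000127). The 3 that fell were Tapbpl (log2 -1.41), Erap1 (-1.38) and Psmb10 (-0.90), named after their values were seen. Of 20 interferon-stimulated genes 3 rose, none fell and 17 were not called, also when adjusted over the list alone (median 0.43, adjusted p = 0.21). Of 16 genes known to be raised by HDAC inhibitors 5 rose, none fell and 11 were not called, also when adjusted over the list alone (median 1.18, adjusted p = 0.00464; 0.369 with an estimated correlation). Mt3, a metallothionein gene of brain, rose 4.31-fold and Gsn, an actin-severing protein gene, 3.94-fold.

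Genes for subunits of the co-repressor complexes that hold HDAC1 and HDAC2 were lower as a list at 24 h. Of 32 such genes 10 fell, 2 rose and 20 were not called, also when adjusted over the list alone (median log2 -0.39, adjusted p = 0.00464; 0.411 with an estimated correlation). Tbl1x (-1.40, adjusted p = 0.00112) and Rcor2 (-1.01, adjusted p = 0.00102) fell. By shLuc level, the share of tested genes that fell ran from 1.87% of the lowest 10% to 31.5% of the highest 10%. Where the members of this list lie in that range was not examined. Whether the co-repressor list fell more than genes of like expression was not tested. Of 16 HDAC genes 2 rose, 2 fell and 12 were not called, also when adjusted over the list alone (median 0.15, adjusted p = 0.423). At 2 h, 1 co-repressor gene rose, 2 fell and 29 were not called, also when adjusted over the list alone (median -0.14, adjusted p = 0.211).

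The remaining lists were not called as lists by camera at 24 h. Of these, fry called p53 targets (higher, adjusted p = 0.00833) and glial genes (lower, adjusted p = 0.00198). The adjusted p-values that follow are from camera. Of 23 pro-apoptotic genes 9 rose, 6 fell and 8 were not called (median log2 0.27, adjusted p = 0.578). Of 24 p53 targets 7 rose, 1 fell and 16 were not called (median 0.21, adjusted p = 0.167). Of 30 immediate-early genes 6 rose (5 adjusted over the list alone), 2 fell and 22 were not called (median 0.30, adjusted p = 0.529). Of 14 glial genes 2 rose, 4 fell and 8 were not called (median -0.74, adjusted p = 0.13). Of 11 non-neural genes 3 rose, 1 fell and 7 were not called (median 0.47, adjusted p = 0.29). Cdkn1a alone rose of 6 inhibitors of cyclin-dependent kinases, with 5 not called (median 0.41, adjusted p = 0.382). Except for immediate-early genes, these counts were the same adjusted over the list alone.

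**Figure D3:**
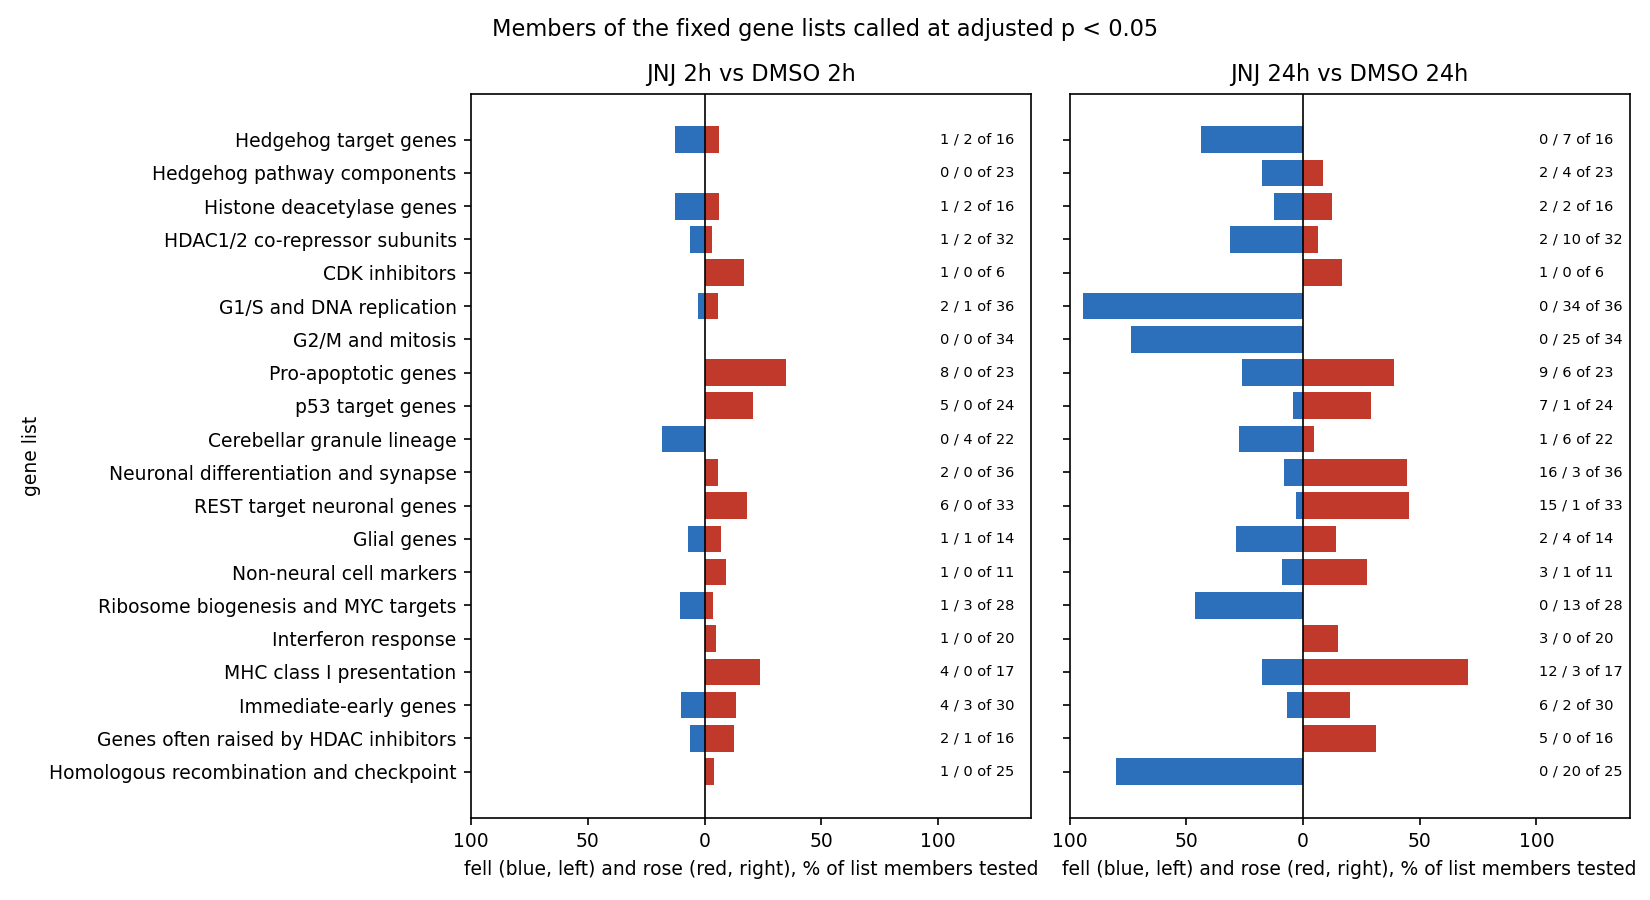
Share of tested members (x axis, %) that rose (red, to the right) and fell (blue, to the left) in each of 20 gene lists (y axis) for JNJ against DMSO at 2 h and at 24 h, with counts beside the bars. G1/S genes go from 2 up and 1 down of 36 at 2 h to none up and 34 down at 24 h.

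The difference between the JNJ effect at 24 h and at 2 h was tested directly, with 3 libraries in each of 4 groups. Between times the effect on Itpr3 differed by a log2 of 6.77, on Scube1 by 5.24, on Plcg2, a phospholipase gene of calcium signalling, by 4.96 and on Dgkk by 4.68. In the other direction Chac1, a glutathione-degrading stress response gene, differed by -3.11, Nradd by -2.85, Ppapdc1b by -2.80 and Rcbtb2 by -2.69 (SE 0.41, adjusted p = 0.00773). In all, 614 genes were called, 363 with a higher effect at 24 h and 251 with a lower one, and 349 and 224 of these differed at least 2-fold. Hdac1 (log2 0.48, adjusted p = 0.277), Hdac2 (0.25, 0.556) and Gli1 were not called. The count was as low as 145 without JNJ 24 h replicate 3 and as high as 1156 without JNJ 2 h replicate 3. The median log2 over all genes was -0.05, and 0.13 by upper quartile or 0.09 by library totals. The higher genes' share, 59.1%, was then 81.8% or 79.9%.

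Other single libraries also moved the count of 614 by more than 1.5-fold. It was 386 without DMSO 2 h replicate 1, 192 without DMSO 2 h replicate 2 and 376 without JNJ 2 h replicate 2. It was 185 and 221 without DMSO 24 h replicates 1 and 3, and 394 and 256 without JNJ 24 h replicates 1 and 2. Chac1 was no longer called with upper-quartile scaling (adjusted p = 0.0502) or library totals (0.0525). Without 1 library, the Chac1 call was lost for DMSO 2 h replicates 1, 2 and 3 (0.0905, 0.0710 and 0.0656) and JNJ 2 h replicates 2 and 3 (0.0694 and 0.0518). It was also lost for DMSO 24 h replicates 1 and 3 (0.0965 and 0.0585) and JNJ 24 h replicates 1, 2 and 3 (0.0834, 0.0660 and 0.115). The Scube1 call was lost without DMSO 2 h replicate 1 (0.0558), DMSO 24 h replicate 1 (0.0501) or JNJ 24 h replicate 3 (0.0558). The Dgkk call was lost without DMSO 2 h replicate 2 (0.0566), DMSO 24 h replicates 1 or 3 (0.0602 and 0.0556) and JNJ 24 h replicates 2 or 3 (0.0517 and 0.0568).

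6 of 20 lists differed between times by camera. The G1/S list was lower at 24 h by a median log2 of -1.18, with 20 of 36 genes called lower, none higher and 16 not called (31 lower adjusted over the list alone; adjusted p = 1.27e-26; 0.142 with an estimated correlation). The homologous recombination list was lower by -1.05, with 5 of 25 genes lower and 20 not called (17 lower adjusted over the list alone; adjusted p = 2.18e-12; 0.506 with an estimated correlation). No G2/M gene was called by edgeR, but the list was lower (median -0.68, adjusted p = 4.02e-08; 0.506 with an estimated correlation), as was the ribosome biogenesis list (median -0.33, adjusted p = 0.0277; 0.686 with an estimated correlation). Neuronal genes were higher at 24 h, with 5 higher, 1 lower and 30 not called, also when adjusted over the list alone (median 0.34, adjusted p = 0.0277; 0.506 with an estimated correlation). Of genes raised by HDAC inhibitors 1 was higher and 15 were not called (2 higher adjusted over the list alone; median 0.62, adjusted p = 0.0277; 0.506 with an estimated correlation). Hedgehog targets (1 lower of 16, adjusted p = 0.0689) and MHC class I genes (none called, 2 higher adjusted over the list alone, adjusted p = 0.0689) were not called to differ between times.

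Of the genes called at both times, 675 were higher at both, where 238 would be shared if the lists were independent, and 458 were lower at both. In opposite directions, 11 were higher at 2 h and lower at 24 h, or 2 the reverse. The log2 changes at both times correlated across genes at r = 0.516 (rho 0.521), with the same sign for 69.5% of genes, though genes are not independent replicates.

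Between DMSO at 24 h and DMSO at 2 h, edgeR called none of 14467 genes. All DMSO 2 h libraries have high and all DMSO 24 h libraries low counts of ribosomal RNA-linked genes, so time cannot be told apart from that library difference. At an unadjusted p under 0.05 there were 1417, DESeq2 called 4 higher and 12 lower, and limma-voom called 2 lower. Hdac1 (log2 -0.03, adjusted p = 0.964) and Hdac2 (-0.03, 0.958) were not called. The groups did not overlap for 17.2% of genes, where chance gives 10%. Without DMSO 2 h replicate 1, 21 genes were higher and 23 lower at 24 h.

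camera called 7 of 20 lists between the DMSO times, with the same confounding. Homologous recombination genes were higher at 24 h (median log2 0.48, adjusted p = 1.7e-08; 0.652 with an estimated correlation) and so were G2/M genes (0.36, adjusted p = 2.2e-07; 0.747 with an estimated correlation). Immediate-early genes were lower (median -0.71, 8 lower adjusted over the list alone, adjusted p = 2.2e-07; 0.652 with an estimated correlation). Hedgehog targets (0.35, adjusted p = 0.00898) and genes raised by HDAC inhibitors (-0.35, 0.0152) moved with adjusted p = 0.652 with an estimated correlation. REST targets (0.33, adjusted p = 0.0123; 0.747 with an estimated correlation) and ribosome biogenesis genes (-0.18, 0.0225; 0.905 with an estimated correlation) also moved.

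In the shRNA libraries, each target was lower with its own hairpin. Hdac1 had 30.6 ± 1.99 CPM in the shHdac1 libraries against 94.7 ± 5.86 in shLuc (log2 -1.63, SE 0.09, adjusted p = 0.000165, n = 3 per group). Hdac2 had 50.3 ± 3.08 CPM in the shHdac2 libraries against 318 ± 23.1 in shLuc (log2 -2.66, SE 0.09, adjusted p = 3.49e-06). The paralog was not called in either: Hdac2 had 321 ± 17.5 CPM with shHdac1 (log2 0.01, adjusted p = 0.977) and Hdac1 103 ± 4.82 CPM with shHdac2 (0.12, 0.533).

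**Figure D4:**
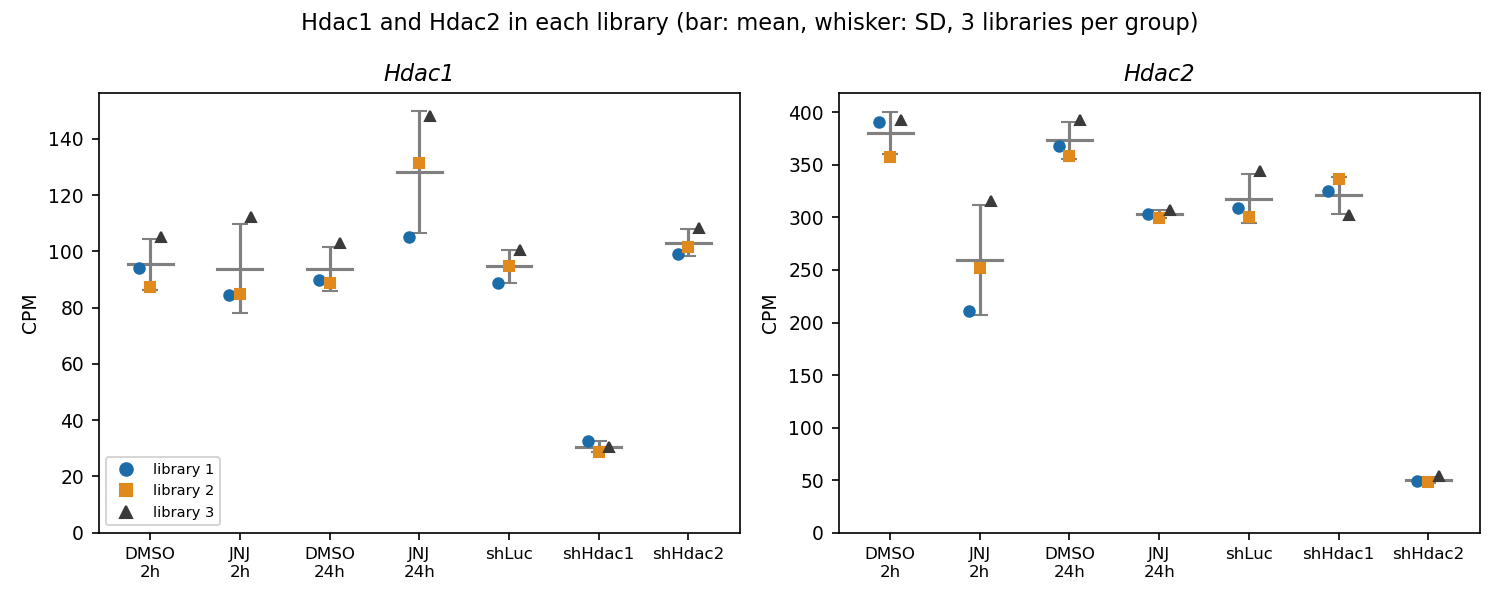
CPM (y axis) of Hdac1 and Hdac2 in every library of the 7 groups (x axis), where points are libraries with a symbol per replicate number, bars the means and whiskers the SD. Hdac1 is 30.6 ± 1.99 CPM in shHdac1 and 94.7 ± 5.86 in shLuc, and Hdac2 is 50.3 ± 3.08 CPM in shHdac2 and 318 ± 23.1 in shLuc.

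Before other genes are read, replicates 1 and 2 of each shRNA group lie very close to each other. Over genes with at least 20 counts, their difference gave a chi-square per degree of freedom of 3.58 in shLuc, 4.25 in shHdac1 and 8.76 in shHdac2, where counting error alone gives 1. All other pairs within a group gave 44.9 to 312. Replicate 3 stands apart in each shRNA group, so much of the spread that the tests use lies between it and the other replicates. Glial genes move with it in part: the myelin gene Mbp, chosen after its values were seen, is higher in replicate 3 than in replicates 1 and 2 by a log2 of 5.98 in shLuc, 3.09 in shHdac1 and 2.98 in shHdac2.

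Beside Hdac1, other genes differed between the shHdac1 and shLuc libraries, and whether this follows from the loss of Hdac1, the hairpin or a library difference was not tested. With shHdac1, Dcx, a microtubule protein gene of young neurons, fell from 134 ± 3.06 to 70.2 ± 13.0 CPM (log2 -0.93, SE 0.14, adjusted p = 0.0267, n = 3 per group). Cpne9, a gene of calcium-dependent membrane binding, fell by a log2 of -2.02 (SE 0.19, adjusted p = 0.0048) and Neurod2, a neuronal transcription factor gene, by -1.47 (SE 0.27, adjusted p = 0.0484). Cpne2, another copine gene, rose 1.74-fold (68.9 ± 2.05 to 120.3 ± 1.06 CPM, SE 0.07, adjusted p = 0.00436). Pgk1, a glycolysis enzyme gene, rose 1.85-fold (249 ± 50.9 to 460.2 ± 26.8 CPM, SE 0.14, adjusted p = 0.0324).

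With shHdac1, 21 genes were higher and 81 lower of 13612 tested, 5 and 30 of them at least 2-fold. The groups did not overlap for 16.7% of genes. Chance gives 10% for 3 independent libraries per group, and more where replicates 1 and 2 lie as close as here. The 16.7% therefore cannot be read as an excess. Other rises were in Slc7a7, an amino acid transporter gene (3.93-fold, 11.3 ± 4.14 against 2.87 ± 0.731 CPM, adjusted p = 0.0324), Dcpp1 (2.90-fold), Pgm2 (2.07-fold) and Adamts9 (1.90-fold). Other falls were in Rhbdl3 (log2 -1.83, adjusted p = 0.0157), Chodl (-1.50, 0.012) and Itga7, a laminin receptor gene (-1.46, 0.0277). A replicate block, which in the shRNA groups mainly takes out the gap between replicate 3 and the others, gave 153 higher and 370 lower. All 102 calls were among them. Without the libraries numbered 3, an alternative added after seeing the data that leaves only the spread between replicates 1 and 2, they were 2961 and 3084. The count of 102 was 6, 8 and 1512 without shLuc replicates 1, 2 and 3, and 10, 2 and 30 without shHdac1 replicates 1, 2 and 3. With replicates 1 and 2 of each group summed into 1 library, an alternative added after seeing the data, none was called by edgeR (534 at an unadjusted p under 0.05). That includes Hdac1, the hairpin's own target. With fewer libraries left, a lost call does not show that a change was smaller.

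The shHdac1 calls rest on few libraries. Apart from Hdac1, 14 of the named genes were called. Cpne2 and Cpne9 lost their calls without shHdac1 replicate 2 only (adjusted p = 0.0570 and 0.0621). Each of the other 12 lost its call without shLuc replicate 1 (adjusted p from 0.0660 for Chodl to 0.190 for Pgm2 over replicates 1 and 2), shLuc replicate 2, shHdac1 replicate 1 or shHdac1 replicate 2. Without shHdac1 replicate 2, Gap43 and Neurod2 had 0.209. Without shHdac1 replicate 3, all of these but Chodl, Dcx and Rhbdl3 lost their calls, with 0.0655 for Slc7a7 and 0.129 for Neurod2. By library totals, Gap43 (0.0604) and Neurod2 (0.0524) lost their calls, and Gap43 also by upper quartile (0.0543).

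camera called 4 of 20 lists with shHdac1, all lower. REST targets had a median log2 of -0.56 with none of 32 called by edgeR (8 lower adjusted over the list alone; adjusted p = 1.18e-09; 0.608 with an estimated correlation). Neuronal genes had -0.36, with 2 of 36 lower, none higher and 34 not called (4 lower adjusted over the list alone; adjusted p = 1.22e-06; 0.612 with an estimated correlation), including Dcx and Gap43, a growth cone protein gene (log2 -1.02, adjusted p = 0.0484). Cerebellar granule lineage genes had -0.35, with 1 of 21 lower, none higher and 20 not called (3 lower adjusted over the list alone; adjusted p = 1.22e-06; 0.291 with an estimated correlation). Zic4 was the gene called (log2 -0.63, SE 0.10, adjusted p = 0.0311). The list of HDAC genes, which holds the hairpin's own target, Hdac1, the only 1 of 15 called (1 higher and 1 lower adjusted over the list alone), had an adjusted p of 0.0377 (median -0.01; 0.291 with an estimated correlation).

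Hedgehog targets were not called with shHdac1: none of 16 by edgeR, 2 lower adjusted over the list alone (median log2 -0.07, adjusted p = 0.0957). Gli1 had 194 ± 7.23 against 186 ± 15.9 CPM (log2 0.06, adjusted p = 0.898). Ptch1 (0.67, 0.574), Hhip (0.37, 0.807), Mycn (-0.42, 0.308), Ccnd1 (-0.26, 0.383) and Atoh1 (-0.87, 0.112) were not called, nor were Cdkn1a (-0.59, 0.193) and H1f0 (0.05, 0.926). With a replicate block, Atoh1 (adjusted p = 0.0127) and Mycn (0.0471) were called lower, and with replicates 1 and 2 summed neither was (0.99963 each).

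With shHdac2, Rcn2, a calcium-binding protein gene of the secretory pathway, fell from 141 ± 10.2 to 57.1 ± 1.77 CPM (log2 -1.30, SE 0.08, adjusted p = 0.000292, n = 3 per group). Gng5, a G protein subunit gene, fell from 26.8 ± 4.33 to 8.54 ± 0.530 CPM (log2 -1.65, SE 0.13, adjusted p = 0.0019). Rd3, known from photoreceptors, rose 3.40-fold (5.63 ± 0.844 to 19.1 ± 1.44 CPM, SE 0.16, adjusted p = 0.00236). Cdkn1a fell from 141 ± 25.9 to 71.2 ± 16.2 CPM (log2 -0.99, SE 0.18, adjusted p = 0.0325), the opposite direction to that with JNJ. Lars2, a mitochondrial tRNA synthetase gene, rose 7.92-fold (116 ± 18.4 to 921 ± 120.4 CPM, log2 2.99, SE 0.52, adjusted p = 0.0297), but it also parts the 21 libraries as the ribosomal RNA precursor Rn45s does. All shLuc libraries lie on the low side of that split and all shHdac2 libraries on the high side.

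With shHdac2, 89 genes were higher and 140 lower of 13612 tested, 25 and 27 of them at least 2-fold. The groups did not overlap for 21.2% of genes, which is no clear excess, since chance gives 10% only for independent libraries. The paralogs Dcpp3 (5.15-fold), Dcpp1 (5.02-fold) and Dcpp2 (4.99-fold) rose, with values that reads shared between them make uncertain. Cxadr, a cell adhesion gene, rose 3.31-fold (adjusted p = 0.0221). Itga7 (log2 -1.60, adjusted p = 0.0146), Gabbr2 (-1.33, 0.00973) and Cntnap1 (-1.31, 0.0142) fell. A replicate block gave 382 higher and 419 lower, with all 229 calls among them. Without the libraries numbered 3, added after seeing the data, they were 3083 and 2969. The count of 229 was 18, 12 and 1212 without shLuc replicates 1, 2 and 3, and 13, 12 and 91 without shHdac2 replicates 1, 2 and 3. With replicates 1 and 2 summed, an alternative added after seeing the data, Hdac2 was the only gene called (adjusted p = 0.0147; 691 genes at an unadjusted p under 0.05).

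Leaving out 1 library ended most of these calls. Hdac2, Rcn2, Gng5 and Rd3 were called without any 1 library, and Dcpp1 lost its call only without shLuc replicate 2 (adjusted p = 0.0508). Lars2, Cxadr, Dcpp2, Dcpp3, Itga7, Gabbr2, Sfrp1, Barhl1, Zic4 and Cdkn1a each lost their calls without shLuc replicate 1, shLuc replicate 2, shHdac2 replicate 1 or shHdac2 replicate 2. Cntnap1 did so for all of these but shHdac2 replicate 1. The adjusted p ran from 0.0539 (Dcpp3 without shHdac2 replicate 2) to 0.193 (Zic4 without shHdac2 replicate 2). Without shHdac2 replicate 3, Lars2 (0.0635), Barhl1 (0.106) and Zic4 (0.0608) lost theirs.

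camera called 3 of 20 lists with shHdac2, all lower. Hedgehog targets had a median log2 of -0.22, with 1 of 16 lower, none higher and 15 not called (7 lower adjusted over the list alone; adjusted p = 0.00152; 0.151 with an estimated correlation). The gene called was Sfrp1, a Wnt antagonist gene (887 ± 64.8 to 544 ± 70.9 CPM, log2 -0.71, SE 0.11, adjusted p = 0.0193). Gli1 (143 ± 18.6 CPM, log2 -0.39, adjusted p = 0.126), Ptch1 (0.25, 0.818), Hhip (-0.21, 0.853), Mycn (-0.10, 0.814), Ccnd1 (-0.35, 0.162), Atoh1 (-0.97, 0.0592) and H1f0 (-0.20, 0.439) were not called. With a replicate block, Atoh1 (adjusted p = 0.00995) and Gli1 (0.0304) were called lower, and with replicates 1 and 2 summed neither was (0.885 and 0.9955). Cerebellar granule lineage genes had -0.08, with 2 of 21 lower, none higher and 19 not called (5 lower and 1 higher adjusted over the list alone; adjusted p = 0.0255; 0.675 with an estimated correlation). These were Barhl1 (log2 -0.80, adjusted p = 0.0373) and Zic4 (-0.52, 0.0362), both cerebellar transcription factor genes. The list of HDAC genes holds the hairpin's own target, Hdac2, the only 1 of 15 called, also when adjusted over the list alone (median -0.01, adjusted p = 0.0117; 0.151 with an estimated correlation).

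Directly between the knockdowns, Neurod2 and Chgb were among the genes lower with shHdac1 than with shHdac2. Neurod2 had a log2 of -1.85 (SE 0.27, adjusted p = 0.0122, n = 3 per group), Chgb, a secretory granule gene, -1.85 (SE 0.27, adjusted p = 0.0123), Rd3 -2.31 (SE 0.16, adjusted p = 0.000347) and Pnmal1 -1.90 (SE 0.33, adjusted p = 0.0228). Higher with shHdac1 were Gng5 (1.73, SE 0.13, adjusted p = 0.000638), Hamp2 (1.54, 0.0102) and Prdm1, a transcriptional repressor gene (1.98, SE 0.41, adjusted p = 0.045). Hdac2 was higher by 2.67 (adjusted p = 3.33e-06) and Hdac1 lower by -1.75 (adjusted p = 4.45e-05).

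In that comparison 121 genes were higher with shHdac1 and 159 lower, 14 and 55 of them at least 2-fold. The groups did not overlap for 26.7% of genes, which is no clear excess, since chance gives 10% only for independent libraries. A replicate block gave 334 and 552, with all 280 calls among them. Without the libraries numbered 3, added after seeing the data, they were 2197 and 2677, and with replicates 1 and 2 summed 1 and 1. The count of 280 was 30 and 40 without shHdac1 replicates 1 and 2, and 37 and 56 without shHdac2 replicates 1 and 2. Without those 4 libraries in turn Prdm1, Hamp2, Pnmal1, Chgb and Neurod2 lost their calls, with adjusted p from 0.0566 (Neurod2 without shHdac2 replicate 2) to 0.206 (Prdm1 without shHdac2 replicate 2). Prdm1 lost its call also without shHdac1 replicate 3 (0.0861), shHdac2 replicate 3 (0.0522) and with upper-quartile scaling (0.0509), and Pnmal1 without shHdac1 replicate 3 (0.0530).

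camera called 5 of 20 lists between the knockdowns. Neuronal genes were lower with shHdac1 (median log2 -0.57), with 5 of 36 lower, none higher and 31 not called (12 lower adjusted over the list alone; adjusted p = 3.61e-11; 0.666 with an estimated correlation). REST targets were lower (median -0.65), with 3 of 32 lower, none higher and 29 not called, also when adjusted over the list alone (adjusted p = 1.71e-09; 0.666 with an estimated correlation). None of 9 non-neural genes was called by edgeR (2 lower adjusted over the list alone; median -1.04, adjusted p = 0.00234; 0.666 with an estimated correlation). Ribosome biogenesis genes (median 0.15, adjusted p = 0.00279) and G1/S genes (median 0.10, adjusted p = 0.0198) were higher with shHdac1, with no gene called in either and 0.801 with an estimated correlation.

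The change with JNJ at 24 h was compared with each knockdown across 13547 genes, which are not independent replicates. It correlated with the shHdac2 change at r = 0.188 and with the shHdac1 change at r = -0.130. Without shLuc replicate 3 these were -0.0554 and -0.292. They were 0.312 and 0.00972 without shLuc replicate 1, and 0.313 and 0.0118 without shLuc replicate 2. Genes lower in both JNJ 24 h and shHdac2 numbered 36, where 22.3 would be shared if independent, and genes higher in both 16, against 14.0. In opposite directions there were 6 (higher with JNJ, 22.6 if independent) and 4 (13.9). With shHdac1, 2 genes were higher in both (3.39 if independent), 10 lower in both (12.9), 15 higher with JNJ and lower with shHdac1 (13.1) and none the reverse (3.35). For JNJ at 2 h, r was -0.108 with shHdac1 and -0.00515 with shHdac2.

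The 200 genes most clearly higher with JNJ at 24 h were higher with shHdac2 as a set (166 tested, median log2 0.21, camera adjusted p = 0.00274) and the 200 most clearly lower were lower (median -0.10, adjusted p = 0.0143), with 0.872 for both with an estimated correlation. With a replicate block the adjusted p were 0.00642 and 0.0367. With shHdac1 neither set was called (adjusted p = 0.0766 and 0.351). Without the libraries numbered 3, an alternative added after seeing the data, the medians of both sets had the opposite sign with shHdac2 (-0.05 for the set higher with JNJ and 0.08 for the set lower with JNJ), and with shHdac1 they were -0.56 and 0.21. Those fits hold only the spread between replicates 1 and 2, which is small and may be technical, so they give no call.

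The 2 knockdowns share their shLuc libraries, which alone makes their changes correlate. Across genes r was 0.510, where 20 simulations with shared controls and no effect of either hairpin gave a mean of 0.504 (0.481 to 0.527). The covariance was 0.0866 against 0.0510 simulated, a difference of 0.0357, and 67.2% of genes had the same sign against 66.8% simulated. Genes higher in both numbered 16 (0.137 if independent) and lower in both 12 (0.833 if independent). No gene changed in the simulations, so their lack of shared calls was fixed in advance and sets no level for these counts. The simulated libraries were also drawn independently, without the closeness of replicates 1 and 2. With 3 shLuc libraries, each knockdown cannot have at least 2 controls of its own. Part of the excess of shared calls over independence may therefore come from the shared controls.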

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

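The tests on ribosomal RNA as a library difference, on Hdac2 knockdown as its cause, on few-count noise in the shHdac1 correlation, on the libraries numbered 3 and on shLuc replicate 3 and same-numbered libraries in the drug-knockdown correlation were chosen only after the result was seen.

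The following differ between 2 h and 24 h by edgeR's test of the difference itself. For 11 of the 20 genes the effect was higher at 24 h. Among genes with a higher effect at 24 h were Itpr3 (log2 1.29 at 2 h and 8.06 at 24 h, adjusted p = 0.00143), Klc3 (1.15 and 6.24, 0.00221), Slc17a7 (1.65 and 4.52, 0.00485) and Gsn (0.22 and 1.98, 0.00773). Others were Plcg2 (-0.75 and 4.21, 0.00868), H2-Ab1 (0.0113), Ret (2.71 and 6.22, 0.0175), Scube1 (0.38 and 5.62, 0.0191), Dgkk (-0.28 and 4.40, 0.0222) and Mapt (1.04 and 2.90, 0.0424). Iba57 fell at 2 h and not at 24 h (-2.14 and -0.03, 0.0175).

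With a lower effect at 24 h were Rcbtb2 (log2 -1.06 at 2 h and -3.75 at 24 h, adjusted p = 0.00773), Ppapdc1b (-0.20 and -3.0003, 0.00773), Lrrc4 (-0.37 and -3.001, 0.0103) and Mcm3 (-0.43 and -1.99, 0.0117). Ccne2 (-0.93 and -2.84, 0.012), Chek1 (-0.68 and -1.998, 0.0307) and Hhip (0.40 and -1.24, 0.0406) join them. So do Nradd (0.56 and -2.29, 0.0147) and Chac1 (0.81 and -2.30, 0.0434). Of the lists, G1/S and replication (1.27e-26), homologous recombination (2.18e-12), G2/M (4.02e-08) and ribosome biogenesis (0.0277) were lower at 24 h by camera, with 0.142, 0.506, 0.506 and 0.686 with an estimated correlation. Neuronal genes and genes raised by HDAC inhibitors were higher (0.0277 each; 0.506 each with an estimated correlation).

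Other splits of the libraries were fitted for every count of called genes. For comparisons of 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The real split called 1982 genes for JNJ at 2 h, 4791 at 24 h, 102 with shHdac1, 229 with shHdac2 and 280 between knockdowns. In each only 1 split, the real one, reached that number, with 0 in the highest other. Every other split puts libraries of both groups together, so any group difference adds to the spread and lowers the count. The counts of 0 therefore cannot decide about chance. For DMSO all 10 splits reached the real count of 0 and the highest other called 6. For the difference between times, 13 of 100 splits, the real one included, called at least 614, the highest other 3774. The other 12 keep the JNJ libraries of each time together, so they still hold the JNJ difference between times. The 85 that mix JNJ libraries call at most 110. These splits therefore cannot decide whether the 614 arose by chance, and do not exclude it.

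Lars2, Mir6236 and Rn45s put the libraries into a low and a high set. Lars2 was 103 to 233 CPM in 10 libraries (both 24 h groups, shLuc and shHdac1 replicate 1) and 577 to 1172 in the other 11, scaled over all libraries. The split was set at the widest gap in Lars2 alone. Both Mir6236 and Rn45s, which overlap ribosomal RNA sequence, part the same libraries (2 of 2). That test was chosen after the pattern of all these genes was seen, so it decides nothing. Ribosomal RNA left in the libraries stays open as an explanation. Knockdown of Hdac2 is argued against, since 8 libraries without that hairpin are in the high set. Whether the same difference moves the other shHdac2 calls stays open. Between DMSO times 225 called genes differed by a median log2 of -0.00682 in the direction of the call (interquartile range 0.564), against 0.711 with shHdac2. That contrast also holds time, and a median near 0 can hide genes that move both ways, so it cannot decide. Between shHdac1 replicates 2 (high set) and 1 (low set), a single pair of libraries, the median over the same genes was 0.0159.

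The shRNA libraries numbered 3 stand apart from replicates 1 and 2, and their effect on counts is given in the next part. Depth is argued against, with a highest ratio of totals of 1.11. RNA from glial cells stays open: the 14 glial genes tested were higher in replicate 3 by a median log2 of 0.94 in shHdac1 and 0.57 in shHdac2 but 0.0824 in shLuc, while the abundant Slc1a2 (414.7 CPM) differed by 0.05, -0.02 and 0.49. A first test averaged over groups gave a lower quartile of 0.184 and was replaced after it was seen by this test per group. That replicates 1 and 2 came from 1 culture may explain the gap and stays open, with a chi-square of at most 8.76 between them, since no label gives the cultures.

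The change with JNJ at 24 h correlates across genes with that of shHdac2 positively and of shHdac1 negatively. The choice of shLuc libraries may set that sign, since r with shHdac2 is -0.0554 without shLuc replicate 3. Noise of genes with few counts is argued against for shHdac2, where r is 0.209 among the 6774 genes with the higher expression, but not for shHdac1, where r goes from -0.130 to -0.0340. That loss of a drug target moves genes as the drug does stays open: between libraries numbered 1, 2 and 3, r was -0.0433, -0.0397 and 0.527 with shHdac2 (mean 0.148, SD 0.328) and -0.345, -0.305 and 0.424 with shHdac1, each pair against the same shLuc library.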

How the results depend on the processing

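The fits without the shRNA libraries numbered 3, with replicates 1 and 2 summed, with a term for the ribosomal RNA-linked split, on its high side alone and with a block in the compared groups only were chosen only after the result was seen, as were the lists without DMSO 2 h replicate 1 and the sets without libraries numbered 3. Over 144 named gene and comparison pairs, 2349 of 2759 values kept their side of the threshold, and 44 of these, not called in either setting, changed sign. A further 44 were newly called, 366 lost a call and no call reversed. Of 1220 list values 1069 kept their side, 38 were newly called and 113 lost a call. Where no construction is named, the cause was not tested. edgeR gave all adjusted p-values unless another tool is named.

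Higher and lower genes at JNJ 2 h were 2103 and 1352 with a replicate block, 476 and 174 with the libraries of both groups only, and 517 and 233 at an adjusted p under 0.01. Lower genes were 1066 by DESeq2 and 1257 with all 21 libraries. At JNJ 24 h they were 4565 and 4383 with a block in the compared groups only and 1563 and 1153 at 0.01. For the difference between times they were 572 and 127 by upper quartile, 823 and 655 by DESeq2, 1142 and 990 with a block, 813 and 909 with all 21 libraries and 36 and 14 at 0.01, and 129 were lower by library totals. Between DMSO times they were 4 and 12 by DESeq2 and 80 and 28 with a block, and 2 were lower by limma-voom and 2 without a filter. With a block as the only added term and all libraries of an experiment, the fits held all calls of the fit without a block. With a block in the compared groups only, 1280 of 1982 calls were held at JNJ 2 h and 4740 of 4791 at JNJ 24 h.

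With shHdac1 they were 175 and 405 by DESeq2, 153 and 370 with a block, 2 and 6 with all 21 libraries, 1 and 4 with both groups only, 1 and 6 at 0.01, 2961 and 3084 without libraries numbered 3, and 0 and 0 with replicates 1 and 2 summed (534 at an unadjusted p under 0.05) or with a block and the ribosomal RNA-linked term (934). With shHdac2 they were 411 and 481, 382 and 419, 5 and 22, 9 and 10, 4 and 11, 3083 and 2969, 0 and 1 summed, and 0 and 0 with both terms (557 unadjusted), in the same order. Between knockdowns they were 360 and 497, 334 and 552, 34 and 42, 241 and 362, 30 and 33, 2197 and 2677, 1 and 1 summed, 44 and 51 with both terms, and 5 and 7 on the high side of the split alone. Without libraries numbered 3 the spread left is that of replicates 1 and 2, which lie very close to each other and may come from 1 culture. These counts are therefore not comparable. The ribosomal RNA-linked term all but coincides with shHdac2 against shLuc, and only shHdac1 replicate 1 parts it from the groups, so that fit can tell little.

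Leaving out each library in turn gave 668 to 2145 higher and 350 to 1220 lower genes at JNJ 2 h, 1967 to 2266 and 1426 to 1760 at JNJ 24 h, 86 to 467 and 59 to 689 for the difference between times, and 0 to 21 and 0 to 23 between DMSO times. With shHdac1 the ranges were 0 to 602 and 2 to 910, with shHdac2 2 to 588 and 8 to 624, and between knockdowns 18 to 107 and 12 to 165. The highest with each knockdown is without shLuc replicate 3, whose fits held all 102 and 229 calls.

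camera with an estimated correlation called 0 lists in each of the 7 comparisons. fry called 1 list at JNJ 2 h, pro-apoptotic genes (higher, adjusted p = 0.0109), and none of those that camera called there. At JNJ 24 h it called all lists that camera called. It also called glial genes (lower, 0.00198), hedgehog pathway components (lower, 0.0204), HDAC genes (higher, 0.00198) and p53 targets (higher, 0.00833). By fry, 0 lists were called between DMSO times, 2 with shHdac1 and 0 between knockdowns. A block with an estimated correlation called 0 for the JNJ comparisons, their difference, DMSO and shHdac2, and 2 with shHdac1 and 2 between knockdowns. Without libraries numbered 3, 7 were called with shHdac1. With the block and ribosomal RNA-linked term 8 were called with shHdac1 and 1 with shHdac2, and summed replicates gave 7 with shHdac2. Without DMSO 2 h replicate 1, 9 were called between DMSO times. The JNJ 24 h sets in shHdac1 without libraries numbered 3 had a median against the JNJ change (adjusted p = 3.34e-12 for the set higher with JNJ and 2.26e-11 for the lower set), tested against the spread between replicates 1 and 2 alone, which cannot carry a call. In shHdac2 they had 0.872 for both with an estimated correlation, and reversed without libraries numbered 3 (0.342 and 0.0513).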

Other observations

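The genes and lists here were chosen only after the result was seen, so each is a hypothesis on the data that raised it. The 23 lists written then were adjusted together.

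Glycolysis and hypoxia genes were higher as a list in both knockdowns: 3 of 25 rose and 22 were not called with shHdac1 (median log2 0.63, camera adjusted p = 2.31e-31; 0.319 with an estimated correlation) and 9 rose and 16 were not called with shHdac2 (0.64, 1.86e-26; 0.224). Pgk1 had 0.89 and 0.98, and Slc2a1, the glucose transporter gene, 0.84 and 0.99. Both knockdowns share the shLuc libraries.

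Of 26 Hox genes 13 rose with JNJ at 24 h (median log2 2.08, camera adjusted p = 0.00136; 0.921 with an estimated correlation) and none was called at 2 h by edgeR. Most Hox genes are barely expressed, and among the 10% of tested genes with the lowest shLuc level, which the filter enriches for genes high in a drug group, 41.4% rose at 24 h. Hoxc13 had 347 counts against 1, a ratio of 444 (exact 95% counting interval 79.2 to 17588), and Hoxa7 310 against 7, a ratio of 56.7 (27.2 to 142). Of 21 ephrins and their receptors 11 rose at 2 h (median 0.95, 1.94e-08; 0.516 with an estimated correlation), with Efna3 at 3.40, Efnb3 at 2.54 and Epha2 at 2.32. Of 20 Wnt and Frizzled genes 6 rose at 2 h (0.71, 8.76e-05; 0.516), led by Wnt7a at 4.80, and 12 rose and 4 fell at 24 h (1.68, 0.00301; 0.921). Of 17 targets of the stress factor ATF4 8 fell and 1 rose at 24 h (-0.89, 0.0176; 0.921), among them Trib3 at -1.48. These directions were the same under RLE, upper-quartile and library-total scaling.

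With JNJ at 24 h, 38 genes had at most 3 counts in each DMSO 24 h library and at least 1 CPM in each JNJ 24 h library, of 8909 genes at or under 3, and 0 the other way. Between DMSO times, cytosolic ribosomal protein genes were lower at 24 h as a list (median -0.59, 2.49e-35; 0.721 with an estimated correlation) with 0 genes called by edgeR.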
